A study of Oryza sativa with 9 samples.

How the data were processed

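Total RNA of dehulled developing rice seeds was made into libraries with a ScriptSeq v2 kit, per the labels' protocols. The 9 libraries belong to 3 genotypes, WT, P1MH (RBP-P G401S) and P3MH (RBP-P A252T), with 3 biological repeats each, per the series' design text. The authors deposited 1 table of RPKM values for 55986 gene loci, per the file headers, with a chromosome and a region for each locus and no gene names or descriptions. The aligner, the counting tool and the genome build are not given in the sources used here. Locus identifiers and coordinates are printed as in the deposited table. All columns of per-sample values were matched to a library by the start of their name, and 0 were left unused.

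Reads were recovered from the spacing of the RPKM values, since a gene's values in a library are multiples of what 1 read is worth. An exon length fitting the values of all libraries was found for 30037 of the 30039 genes above 0 in any library (99.993%), with a relative tolerance of 1e-05 on single steps. The smallest fitting length was taken, and it was the only one possible within the gene's span for 14662 genes. For the others the length, and with it the recovered reads of the gene, may be too small. The totals recovered were 5865007 to 7498434 reads per library, of which 88.9 to 90.6% lay in genes, a share that too small lengths would understate. Among the low values, 920 in the WT libraries and 9 in the mutant libraries lay on a step of 0.5 read. The floor of a gene with no reads was set at 3 reads per library, and covers counting error only, as the reads carry no molecular identifiers.

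The test fixed before the data were examined for normalized values was limma with a mean-variance trend and robust moderation, on log2(RPKM + 1), for genes with a mean of at least 1 RPKM over all libraries. This left 16064 genes. All 9 libraries entered 1 fit with 1 coefficient per genotype, and p-values were adjusted by Benjamini-Hochberg within each comparison at a false discovery rate of 0.05. A fold change on this scale understates the change of low genes. P-values measure the spread between repeats within genotypes, pooled over all 9 libraries and moderated across genes. Relative to its mean, the residual variance was 0.662 in WT, 1.27 in P1MH and 1.07 in P3MH. Pooling may thus make the tests between the mutants too liberal. R 4.3.3, limma 3.58.1, Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9 were used. Shared calls of the 2 mutants were set beside 20 simulations of unchanged groups against the same WT libraries.

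Gene names came from the RefSeq gene table of the assembly ASM3414082v1, which does not hold the identifiers of the deposited table, so names were matched by hand and checked. A name counted as checked when a gene of that name lay on the same chromosome, its span was 0.8 to 1.25 times that in the deposited table, and its order along the chromosome fitted the other checked names. The span window was set after a first look at the span ratios, and 2 names were dropped for their order. Gene lists fixed before the data were examined could be used only where they gave loci, since the table holds no descriptions. Of 46 such loci 44 were used, and 19 of these had a checked name. One fixed locus was left out because its position belonged to another gene (HSP101 in place of a trafficking factor). The other 25 stayed in their lists and are not named. Lists of glutelins, prolamines, embryo and aleurone, cell cycle, photosynthesis, heat shock, sucrose and carbon supply, clock, alpha-amylase and housekeeping genes, and 1 more ER protein folding gene, were filled by hand after the table was opened. Their members were chosen before any test value was seen, except 3 seed allergens chosen after their values were seen. Of 97 such loci 61 had a checked name and were used. RBP-P was located by the spans of 5 neighbouring genes, a window chosen after looking. Their mean difference from the RefSeq spans was 2.6% at LOC_Os01g16090, against 8.2% for the next best of 111860 runs compared.

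Lists with at least 5 tested members were tested with camera (preset correlation 0.01, and again with an estimated correlation) and with fry. Camera compares a list with the other genes, while fry tests the changes of the list's own members. The p-values of each were adjusted over the lists of both comparisons against WT together and separately between the mutants. The rule for named genes took RBP-P and the 3 highest members of each list fixed by locus, and these are printed where the name was checked: BEI, AGPS2, NF-YB1, VPE1, PDIL1-1, BiP1 and PDIL2-3. The parts of the rule that needed descriptions named nothing. Every other gene is named as a member of its list or was chosen after its values were seen.

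The alternatives tried were a replicate block, median-ratio, quantile and upper-quartile rescaling, scaling without the 50 highest genes, no filter, a mean of at least 5 RPKM, a pseudocount of 0.1, limma without trend and robust moderation, only the 2 genotypes compared, a 2-fold threshold, and each library left out. Added after the data were seen were limma-voom on the recovered reads, leaving out genes on in one line and off in the other, and a recovered exon length of at least 1000 bases. The limma step was tested on simulated data for P1MH against WT with 16064 genes. Of the genes with a mean of at least 5 RPKM, 200 were changed, and a further 12 were shifted by -0.7 as a list. Among the 200, it recovered 92% of changes of log2 size 1 and 100% of log2 size 2, with 9 false calls and 0 of the wrong sign. The simulated errors were independent between genes and had the same variance in all genotypes. Recovery was not simulated for genes under 5 RPKM, although 9047 of the 16064 tested genes had a mean of at least 5. The read recovery was tested on simulated data of 3000 genes and returned all 9 totals. Its exon lengths were right for 100% of the simulated genes with only 1 possible length, and were not checked for the others. The share of ribosomal and organelle RNA was not computed, since no locus could be named as such.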

Results

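RNA-seq was used to compare seed transcripts of wild-type rice (Oryza sativa) with 2 lines that each carry an amino acid change in RBP-P. RBP-P is an RNA-binding protein that binds the messenger RNAs of seed storage proteins. The line P1MH carries G401S and the line P3MH carries A252T. Dehulled developing seeds were taken 10 to 14 days after flowering from plants grown at 27 °C with 12 h of light and 12 h of dark. Each genotype had 3 biological replicates, 9 libraries in all, and the deposited values are RPKM (reads per kilobase of exon, scaled to the mapped reads of the library). The total per library, recovered from the spacing of the RPKM values, was 6814570, 7498434 and 7083494 reads in wild type (WT), 5865007, 6460464 and 6522918 in P1MH, and 6479755, 6062155 and 7379192 in P3MH. At 1 kilobase of exon, 3 reads corresponded to between 0.40 and 0.51 RPKM. The 10 highest genes held 30.9 to 33.9% of all RPKM in WT, 37.8 to 39.6% in P1MH and 33.7 to 37.2% in P3MH. Of the low values tested, 17.6 to 20.1% lay midway between whole reads, on steps of 0.5 read, in the WT libraries and at most 0.184% in any mutant library. The cause of this difference was not tested, and it runs with genotype in both comparisons against WT.

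The level of the mutated gene was examined first. RBP-P transcript was 13.9 ± 1.94 RPKM in WT, 9.43 ± 2.09 in P1MH and 9.50 ± 2.14 in P3MH (SD, n = 3 each). Every one of the 6 mutant libraries lay below all 3 WT libraries. The log2 fold change was -0.53 (SE 0.19, limma adjusted p = 0.107) in P1MH and -0.52 (SE 0.19, limma adjusted p = 0.151) in P3MH, so neither difference passed the test. P1MH and P3MH differed by -0.01 (limma adjusted p = 0.991). The locus, LOC_Os01g16090, spans 9063968 to 9066787 of chromosome 1 in the coordinates of the deposited table. Both mutations are single amino acid changes, so the transcript level does not check the genotype labels.

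The first comparison asked which seed transcripts differed between P1MH and WT. Several genes of DNA replication fell and several embryo or aleurone genes rose in P1MH. PCNA, the sliding clamp of DNA polymerase, fell from 14.3 ± 1.87 RPKM in WT to 6.91 ± 1.36 in P1MH (SD, n = 3 each; log2 fold change -0.96, SE 0.16, limma adjusted p = 0.0027). MCM5, a subunit of the replicative helicase, fell from 7.09 ± 1.55 to 2.85 ± 0.304 RPKM (log2 fold change -1.06, SE 0.18, limma adjusted p = 0.0027). RAB16A, a dehydrin, rose from 49.3 ± 22.8 to 175 ± 53.8 RPKM (log2 fold change 1.85, SE 0.33, limma adjusted p = 0.00586). OLE18, an oleosin of oil bodies, rose from 339 ± 32.4 to 666 ± 147 RPKM (log2 fold change 0.95, SE 0.20, limma adjusted p = 0.0103).

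Of the 12 genes of the cell cycle and DNA replication list, 6 fell in P1MH and none rose, and 9 fell when adjusted over the list alone. The 6 were PCNA, MCM2, MCM3, MCM5, MCM6 and MCM7, and the list's median log2 fold change was -0.81. The list lay lower than the other genes by limma's camera with a preset correlation of 0.01 (adjusted p = 2.46e-05), but not with an estimated correlation (adjusted p = 0.433). By fry its adjusted p was 0.00952. Of 7 measured embryo and aleurone genes, 4 rose (RAB16A, RAB16B, RAB16C and OLE18), as did 4 when adjusted over the list alone. Their list had a median of 0.95 (camera adjusted p = 2.46e-05 with the preset correlation and adjusted p = 0.433 with an estimated correlation, fry adjusted p = 0.0223). LEA3 and Em, late embryogenesis genes of the same list, had log2 fold changes of 0.67 and 0.83 that did not pass the test. VP1, the last member not called, had one of 0.14 (limma adjusted p = 0.783). RAB16A, RAB16B and RAB16C lie together on chromosome 11, within 15327768 to 15343857, and reads shared between them were not tested. In WT, RAB16B and RAB16C stood at 1.51 ± 0.665 and 0.300 ± 0.220 RPKM (SD, n = 3), the latter near the floor of 3 reads. The members of both lists were chosen after the table was opened and before any test value was seen.

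Among 7 glutelin genes, which encode the main storage proteins of rice endosperm, GluA-1 and GluA-2 rose in P1MH and the other 5 did not pass the test. GluA-1 went from 13988 ± 1475 to 22462 ± 1866 RPKM (log2 fold change 0.69, limma adjusted p = 0.0464). GluA-2 went from 10668 ± 981 to 17374 ± 973 RPKM (log2 fold change 0.71, limma adjusted p = 0.0369). The list as a set had a camera adjusted p of 0.0509 and a fry adjusted p of 0.00636, and the same 2 genes passed when adjusted over the list alone. Both calls were lost under quantile normalization and with the replicate number as a block, and glutelin genes are similar enough to share reads. The 7 glutelin genes together held 18.3 ± 0.798% of all RPKM in WT, 24.3 ± 1.25% in P1MH and 22.5 ± 0.964% in P3MH (SD, n = 3 each).

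Of 28 starch synthesis genes, 3 fell and none rose in P1MH (4 fell when adjusted over the list alone; camera adjusted p = 0.737). The 3 belong to the 18 members whose names could not be checked and are not named here. Of the 3 calls, 2 were kept under median-ratio and upper-quartile rescaling, with the replicate number as a block and when scaled without the 50 highest genes, and 1 under quantile normalization. BEI, a starch branching enzyme, was 2320 ± 221 RPKM in WT and 2004 ± 326 in P1MH, and AGPS2, a subunit of ADP-glucose pyrophosphorylase, was 1615 ± 156 and 1299 ± 110. Neither passed the test (limma adjusted p = 0.497 and 0.269). NF-YB1, an endosperm transcription factor, fell from 197 ± 16.6 to 121 ± 12.9 RPKM (log2 fold change -0.70, SE 0.16, limma adjusted p = 0.0157) and was the 1 member of 5 in its list to pass, also when adjusted over the list alone (camera adjusted p = 0.907). No member of the 6 glutelin trafficking factors passed, also when adjusted over the list alone (camera adjusted p = 0.737). VPE1, the protease that matures glutelins, had a log2 fold change of -0.21.

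None of the 5 ER protein folding genes passed over all genes tested, while 3 were lower when adjusted over the list alone (camera adjusted p = 0.0663, fry adjusted p = 0.0416). PDIL1-1, a protein disulfide isomerase, was 2381 ± 23.4 RPKM in WT and 1468 ± 197 in P1MH (log2 fold change -0.71, SE 0.21, limma adjusted p = 0.0532). BiP1, an ER chaperone, had a log2 fold change of -0.44 and PDIL2-3 one of -0.46. Among 6 heat shock genes HSP26.7, a small chaperone of plastids, fell from 14.9 ± 2.47 to 3.69 ± 0.599 RPKM (log2 fold change -1.75, SE 0.25, limma adjusted p = 0.000834). RBCS2, the small subunit of Rubisco, and plastocyanin fell among 4 photosynthesis genes (log2 fold changes -0.85 and -0.66). SUS3, a sucrose synthase, and PPDKB, a pyruvate orthophosphate dikinase, fell among 8 genes of sucrose and carbon supply (log2 fold changes -0.79 and -0.73). Adjusted over each list alone, 2 genes each were lower in the heat shock, photosynthesis and sucrose lists. The sucrose list passed by fry (adjusted p = 0.00487) and not by camera (adjusted p = 0.528). The 6 circadian clock genes gave no call and a median of -0.09 (camera adjusted p = 0.892).

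Across the genome, limma called 511 genes higher and 905 lower in P1MH than in WT, out of 16064 tested, and 243 and 328 of these changed at least 2-fold. The libraries of the 2 genotypes did not overlap for 31.2% of all tested genes, where chance gives 10%. The median gene stood at -0.10, and rescaling by the median ratio, which moved it to -0.01, gave 659 higher and 577 lower. The calls of the 6 cell cycle and 4 embryo genes held under all 4 rescalings tried. With libraries left out in turn, that of RAB16C was lost without 7 of the 9 (and with the replicate number as a block), those of MCM6 and MCM7 without 3 each and that of OLE18 without 1. The calls of plastocyanin and PPDKB were lost under median-ratio rescaling and those of NF-YB1 and SUS3 under quantile normalization (SUS3 also when scaled without the 50 highest genes).

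**Figure D1:**
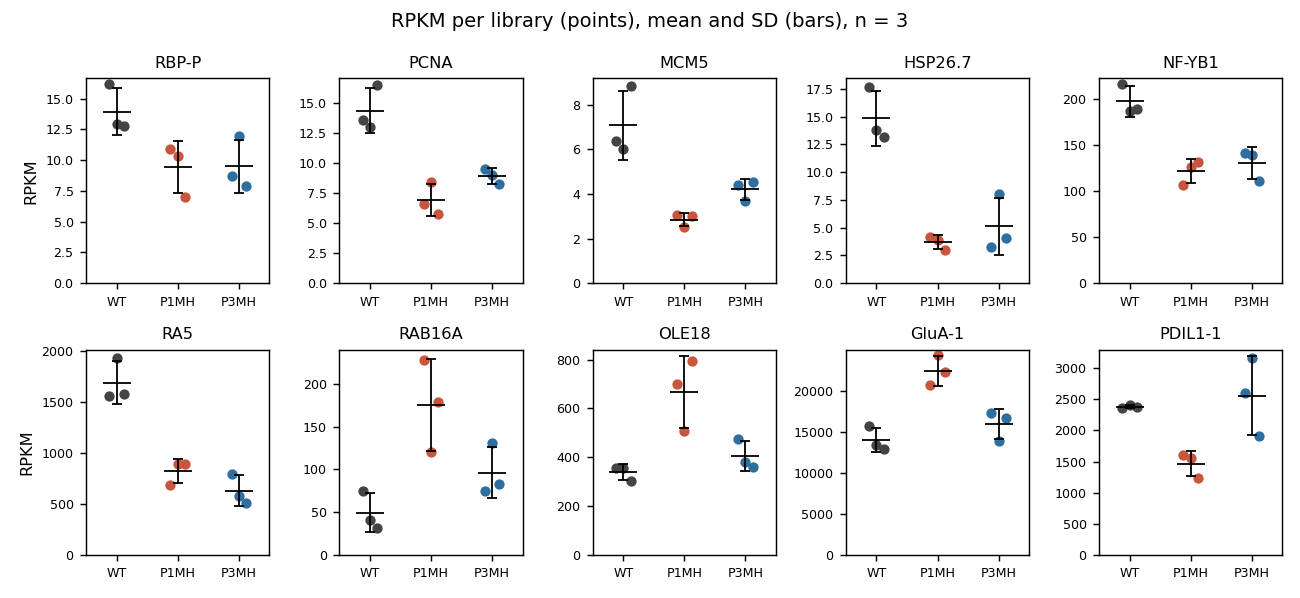
RPKM of 10 genes in each library (points) with the mean and SD of each genotype (bars, n = 3), for WT (grey), P1MH (red) and P3MH (blue); the vertical axes are linear, start at 0 and differ between genes. PCNA has a mean of 14.3 RPKM in WT, 6.91 in P1MH and 8.90 in P3MH, and RAB16A has 49.3, 175 and 96.0.

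The second comparison asked which seed transcripts differed between P3MH and WT. HSP26.7 fell from 14.9 ± 2.47 RPKM in WT to 5.13 ± 2.56 in P3MH (SD, n = 3 each; log2 fold change -1.44, SE 0.25, limma adjusted p = 0.0045). PCNA fell to 8.90 ± 0.636 RPKM (log2 fold change -0.63, SE 0.16, limma adjusted p = 0.0425), NF-YB1 to 130 ± 17.0 RPKM (log2 fold change -0.60, limma adjusted p = 0.0464) and RBCS2 to 7.89 ± 1.08 RPKM (log2 fold change -0.64, limma adjusted p = 0.0405). These last 3 calls were lost under all 4 rescalings and with the replicate number as a block. No glutelin gene passed the test, over all genes or when adjusted over the list alone, and GluA-1 was 15953 ± 1854 RPKM in P3MH (log2 fold change 0.19, limma adjusted p = 0.631).

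Of the 12 cell cycle genes, 1 fell in P3MH (2 when adjusted over the list alone) and the median was -0.55. The list lay lower than other genes by camera with the preset correlation (adjusted p = 0.00171) and not with an estimated correlation (adjusted p = 0.447). By fry its adjusted p was 0.028. None of the 7 embryo and aleurone genes passed over all genes tested, and 2 were higher when adjusted over the list alone. RAB16B was called higher under quantile normalization and when scaled without the 50 highest genes. The embryo and aleurone list did not pass by fry (adjusted p = 0.121). It had a median of 0.75 (camera adjusted p = 0.00075 with the preset correlation, adjusted p = 0.433 with an estimated correlation). This median is the value of Em, which was 71.9, 195 and 69.9 RPKM in P3MH replicates 1, 2 and 3. LEA3 was 96.6, 263 and 111 RPKM, so both stood far higher in replicate 2. RAB16A was 96.0 ± 29.9 RPKM in P3MH (log2 fold change 1.0, SE 0.33, limma adjusted p = 0.117). Of the 28 starch synthesis genes, 1 fell, again 1 whose name could not be checked, also when adjusted over the list alone (camera adjusted p = 0.907). No ER protein folding or trafficking gene passed, also when adjusted over each list alone (camera adjusted p = 0.737 and 0.772). PDIL1-1 was 2561 ± 633 RPKM and BiP1 was 1888 ± 615. Of the 5 transcription factors 1 was lower and 2 were higher when adjusted over the list alone (camera adjusted p = 0.286). Under 3 of the 4 rescalings 1 member whose name could not be checked was called higher, and NF-YB1 lost its call under all 4. The glutelin list had a camera adjusted p of 0.0509 and a fry adjusted p of 0.0179. Neither the 8 genes of sucrose and carbon supply nor the 6 clock genes gave a call over all genes tested. The sucrose list passed by fry (adjusted p = 0.0202) and not by camera (adjusted p = 0.892). When adjusted over each list alone, 1 gene of sucrose and carbon supply, 2 photosynthesis genes and 1 heat shock gene were lower.

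**Figure D2:**
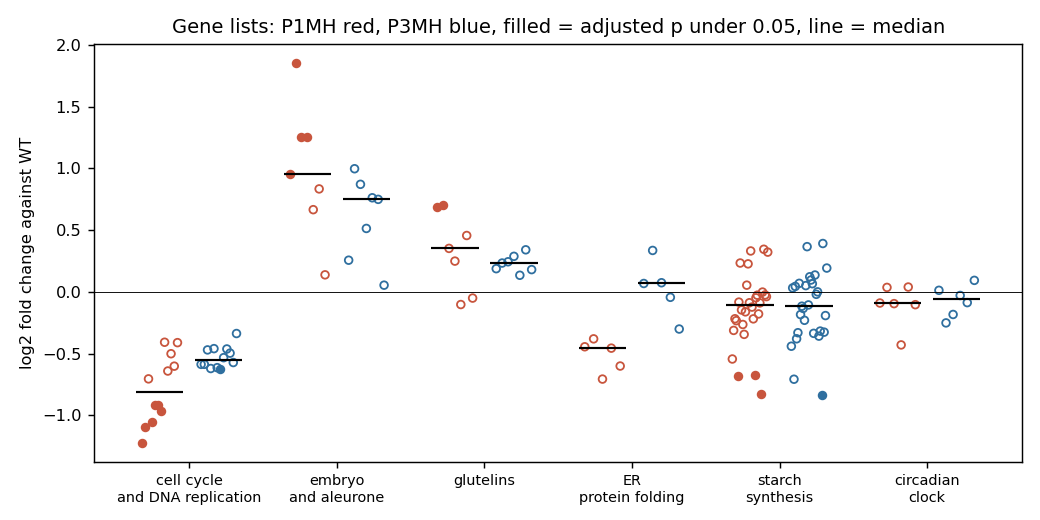
Log2 fold change against WT of each gene of 6 lists (1 circle per gene), for P1MH (red) and P3MH (blue); filled circles had a limma adjusted p under 0.05 over all genes tested, and the line is the list's median. The cell cycle genes lie below 0 in both mutants, with medians of -0.81 and -0.55, and the embryo and aleurone genes above it, with medians of 0.95 and 0.75. The median of 0.75 is the value of Em, which was 71.9, 195 and 69.9 RPKM in P3MH replicates 1, 2 and 3.

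Across the genome, limma called 268 genes higher and 498 lower in P3MH than in WT, and 158 and 259 of these changed at least 2-fold. The 2 genotypes' libraries did not overlap for 27.6% of tested genes. The median gene stood at -0.13, and median-ratio rescaling moved it to -0.01 and gave 389 higher and 335 lower.

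The 2 mutants were then set side by side to ask which genes differed from WT in both. HSP26.7, PCNA, NF-YB1 and RBCS2 fell in both, though the P3MH calls of PCNA, NF-YB1 and RBCS2 were lost under all 4 rescalings. Limma called 188 genes higher in both mutants, 296 lower in both and none in opposite directions. Independent lists of these sizes would share 8.53 and 28.1 genes, and in 20 simulations of unchanged groups against the same WT libraries no gene was shared. Across genes, the fold changes of the 2 comparisons correlated at 0.79, against 0.36 in the simulations, and their covariance was 0.202 against 0.0159, a difference of 0.186. Genes are not independent replicates, and the 3 WT libraries are too few to split, so part or all of the excess may come from the shared controls. The simulations held no offset common to all 3 WT libraries. With median-ratio rescaling, the shared genes were 251 higher and 205 lower.

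**Figure D3:**
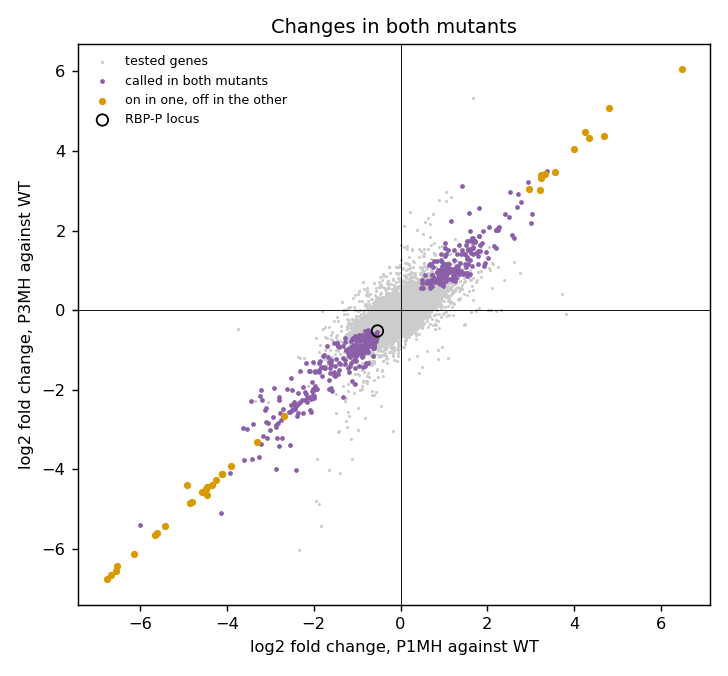
Log2 fold change against WT of each of the 16064 tested genes in P1MH (horizontal) and P3MH (vertical). Grey points are tested genes, and purple and orange points together are the 484 genes called the same way in both mutants. Orange points are the 34 of these that were on in every library of WT and off in every mutant library, or the reverse. The open circle is RBP-P, at -0.53 and -0.52.

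The direct comparison of the mutants asked whether the 2 amino acid changes gave different transcript levels. Limma called 5 genes, 2 higher and 3 lower in P1MH than in P3MH, out of 16064 tested. All 5 have no name in the sources used here and were picked for mention after their values were seen. LOC_Os12g28015 was 18.2 ± 7.59 RPKM in P1MH and 1.65 ± 0.969 in P3MH (SD, n = 3 each; log2 fold change 2.85, limma adjusted p = 0.0363). LOC_Os06g07960 was 3.38 ± 1.33 RPKM in P1MH and listed at 0 in all 3 P3MH libraries (fitted log2 fold change 2.09, limma adjusted p = 0.0279). LOC_Os01g16140 was 9.27 ± 0.678 and 27.6 ± 4.77 RPKM (log2 fold change -1.47, limma adjusted p = 0.0117), LOC_Os05g01810 was 7.39 ± 1.78 and 19.9 ± 4.21 (-1.32, limma adjusted p = 0.0363), and LOC_Os12g02200 was 5.90 ± 0.447 and 12.5 ± 1.0 (-0.97, limma adjusted p = 0.0421). At an unadjusted limma p under 0.05, 2054 of the 16064 tested genes passed, a threshold that unchanged genes pass at a rate of 0.05.

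No member of any named list passed over all genes tested between the mutants. Adjusted over each list alone, P1MH was lower at 1 ER protein folding gene, 1 trafficking factor, 1 transcription factor and 1 gene of sucrose and carbon supply. It was higher at 2 genes of sucrose and carbon supply, 1 embryo and aleurone gene, 1 starch synthesis gene, and the only tested members of the prolamine and alpha-amylase lists. The other loci of these last lists had no checked name or fell below the filter. The ER protein folding list lay lower in P1MH than in P3MH by camera (median -0.51, adjusted p = 0.00107), and so did the cell cycle list (median -0.27, adjusted p = 0.0090). Neither did with an estimated correlation (camera adjusted p = 0.408 for both) or by fry (adjusted p = 0.0802 and 0.238). PDIL1-1 differed by -0.78 (SE 0.21, limma adjusted p = 0.194) and PCNA by -0.34 (limma adjusted p = 0.407). The embryo and aleurone list had a median of 0.38 (camera adjusted p = 0.0559) and the glutelin list one of 0.11 (camera adjusted p = 0.654). The count of 5 genes became 238 without P1MH replicate 3 and 0 without P1MH replicate 1.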

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

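Of the tests of this part, the splits of the libraries were chosen after the result was seen. The results below stand out because the 2 mutants differed from each other by a direct test.

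The 5 genes that differed between P1MH and P3MH had log2 fold changes of 2.85 (LOC_Os12g28015), 2.09 (LOC_Os06g07960), -0.97 (LOC_Os12g02200), -1.32 (LOC_Os05g01810) and -1.47 (LOC_Os01g16140). In WT LOC_Os12g28015, LOC_Os06g07960, LOC_Os12g02200, LOC_Os05g01810 and LOC_Os01g16140 stood at 19.9 ± 5.11, 1.44 ± 0.747, 8.11 ± 0.879, 19.7 ± 0.875 and 8.28 ± 1.48 RPKM (SD, n = 3). By limma P3MH alone passed against WT at LOC_Os12g28015, LOC_Os01g16140, LOC_Os06g07960 (adjusted p = 0.0198) and LOC_Os12g02200 (log2 fold change 0.57, adjusted p = 0.0373), and P1MH alone at LOC_Os05g01810. At LOC_Os06g07960 and LOC_Os12g02200 the means of the 2 mutants lay on opposite sides of WT, and P1MH did not pass (limma adjusted p = 0.069 and 0.105). The 10 splits of the 6 mutant libraries are too few for a share under 0.05. The real split gave 5 genes, the highest of the others 1, and 1 split, the real one, gave as many. With 1 library left out, LOC_Os05g01810 and LOC_Os12g02200 kept their calls between the mutants only without P1MH replicate 3. LOC_Os12g28015 kept its call only without P1MH replicate 3 or WT replicate 1, and the other genes lost theirs without some libraries. Against WT, the P3MH call of LOC_Os12g02200 was lost without any 1 WT or P3MH library. That of LOC_Os06g07960 was lost without replicate 1 or 2 of WT or of P3MH. The lists of cell cycle genes (camera adjusted p = 0.0090) and ER protein folding genes (camera adjusted p = 0.00107) also differed between the mutants, each lower in P1MH, and neither did with an estimated correlation (adjusted p = 0.408).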

How the results depend on the processing

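The settings voom, without on-off genes and exon length of at least 1000 were chosen after the data were seen. P1MH against WT kept within 1.5 times of its 1416 genes under every setting but the 2-fold threshold (571) and leaving out libraries (622 to 1457; 923 without WT replicate 1, 715 without WT replicate 2 and 622 without WT replicate 3). P3MH against WT (766) fell to 436 with a mean of at least 5 and 417 with the 2-fold threshold, and ranged from 365 to 896 with a library left out (452, 394 and 365 without WT replicates 1, 2 and 3, and 440 without P3MH replicate 2). The shared genes (484) were 301 with a mean of at least 5, 264 with the 2-fold threshold, and 253 to 450 with a library left out (276 without WT replicate 2, 253 without WT replicate 3). The 5 genes between the mutants became 0 with no filter, 2 with a pseudocount of 0.1, 3 without trend and robust moderation, 3 with only the 2 genotypes compared, 11 when scaled without the 50 highest genes, 20 with voom and 15 with an exon length of at least 1000. They ranged from 0 to 238 with a library left out, 238 being without P1MH replicate 3 and 0 without P1MH replicate 1, P3MH replicate 1 or P3MH replicate 2. Fewer genes tested, a higher threshold or fewer libraries are part of these settings, and the cause was not tested for the rest. Voom on recovered reads called 1547 and 861 genes against WT and 548 shared genes, and leaving out the on-off genes gave 1359, 702 and 438.

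The number of lists called by camera with the preset correlation (4) was 2 with a mean of at least 5, 6 without on-off genes and 4 to 7 with a library left out. All 4 are the cell cycle and embryo lists in both comparisons against WT. With an estimated correlation all 4 calls were lost (adjusted p = 0.433 and 0.447 for the cell cycle list in P1MH and P3MH, 0.433 for the embryo list in both). With the preset correlation they were kept under every alternative in which they were tested. A mean of at least 5 left both lists under 5 members and untested, and an exon length of at least 1000 the embryo list; the glutelin list was called in both mutants under each. None of the lists fixed before the data were examined was among the 4. RBP-P stayed below the threshold against WT, with -0.64 to -0.35 in P1MH and -0.68 to -0.41 in P3MH over libraries left out. Between the mutants it was 0.035 when scaled without the 50 highest genes and -0.12 to 0.17 with a library left out. Of 940 values of the 42 called gene results under alternatives, 736 kept their call, 204 lost it and 0 turned. HSP26.7 in both mutants and RAB16A, RAB16B, MCM2, MCM3 and MCM5 in P1MH kept theirs under all alternatives in which they were tested (RAB16B and MCM5 were not tested with a mean of at least 5, nor HSP26.7 with an exon length of at least 1000), while the calls of NF-YB1, PCNA and RBCS2 in P3MH and of GluA-1 and GluA-2 in P1MH were lost in many. Of the 9 libraries left out, 5 ended the P1MH calls of PPDKB and of plastocyanin, 4 that of SUS3 and 3 that of NF-YB1. Leaving out WT replicate 2 or 3 or P1MH replicate 3 ended the calls of MCM6 and MCM7 in P1MH, WT replicate 3 that of OLE18 (0.87) and WT replicate 2 that of RA5 (-0.94).

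Replicate numbers do not pair the libraries: deviations of same-numbered pairs correlated at -0.31 to 0.11, and 2 of 9 libraries correlated best with their own number. A replicate block gave 1178, 650 and 5 genes and ended the calls of GluA-1, GluA-2 and RAB16C in P1MH, of PCNA, NF-YB1 and RBCS2 in P3MH, and of LOC_Os12g02200 in P3MH and between the mutants. Depth limits genes near 1 RPKM, and the steps of 0.5 read in WT limit both comparisons against WT.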

Other observations

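Of the tests of this part, those chosen after the result was seen were the splits of the libraries, the tests on genes on in one side and off in the other, on the shared WT libraries and on values at steps of 0.5 read, those on storage share, embryo share and seed stage, and the test on the distance to RBP-P.

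Seed allergen genes of the albumin family, chosen after their values were seen, went opposite ways. RAG1 rose from 0.217 ± 0.112 RPKM in WT to 109 ± 22.8 in P1MH and 80.7 ± 18.8 in P3MH (SD, n = 3 each; limma adjusted p = 1.31e-10 and 3.08e-10). RA5, also on chromosome 7, fell from 1690 ± 213 to 823 ± 118 and 630 ± 149 RPKM (log2 fold changes -1.04 and -1.44, limma adjusted p = 0.00787 and 0.00101), and its call in P1MH was lost under quantile normalization. RAG2, also on chromosome 7, had log2 fold changes of -0.16 and -0.62 that did not pass. PROLM25, a prolamine, was 3276 ± 314 RPKM in WT, 5682 ± 1434 in P1MH and 3087 ± 848 in P3MH, and passed in neither (limma adjusted p = 0.0812 and 0.827). No exon length fitted the values of PROLM25, and WT replicate 3 and P3MH replicate 1 were both listed at 3273.33 RPKM. Other prolamine loci had no checked name and were left out. Actin 1 had log2 fold changes of -0.40 and -0.27, and AMY3E, an alpha-amylase, -0.02 and -0.76, none of which passed over all genes tested. Taken alone, as lists of 1 tested gene with a checked name, PROLM25 and actin 1 passed in P1MH and AMY3E in P3MH.

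A locus of very high level, LOC_Os05g26386, spanned 8141 to 26617 RPKM in the WT libraries and 90.7 to 775 in the mutant libraries (limma adjusted p = 0.00475 in P1MH and 0.011 in P3MH). The call in P3MH was lost without WT replicate 2 or WT replicate 3, where the log2 fold change was -5.07 and -5.22. It has no name in the sources used here, its level varied more than 3-fold between WT libraries, and reads shared with similar genes were not tested.

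Between WT and both mutants 34 genes were on in every library of one side (at least 5 RPKM) and under 5% of that level in every library of the other, and no other of the 84 splits of 3 against 6 libraries gave any. Of these, 22 were on in WT, 17 of them with no reads in all 6 mutant libraries, and 12 were on in the mutants, RAG1 among them. LOC_Os06g50742 was at least 210-fold lower in the mutants and LOC_Os01g05530 at least 45.3-fold higher, taking the lowest library of the higher side against a floor of 3 reads per library, and without the 34 genes 438 of the 484 shared calls were kept. Reads shared with near-identical copies remain open for the 22, since 10 of them had exactly the span of another of the set on another chromosome (95th percentile of 10000 random sets: 0). They remain open for the 12 as well: 0 of these did, which random sets give too and so says nothing against it. A WT of another genetic background than both mutant lines may also account for either set, and cannot be told apart from the mutations, as the 2 lines share it and 0 genes were on in one line and off in the other.

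The shared fold changes of the 2 mutants are the second pattern. Random spread of the WT libraries in common is not their whole source, since the covariance of 0.202 lay above the highest simulated value of 0.0169. After a trend on the recovered exon length was removed from each library, 406 of the 484 shared calls stayed. The recovered length may be too small for genes where it was not the only one possible. The test therefore cannot exclude a trend on the true length. The simulations held no offset common to all WT libraries, which would enter both comparisons. They therefore cannot exclude the shared WT as the source. A different counting of WT reads, which was not tested directly, cannot be told apart from genotype, as 920 values on a step of 0.5 read lay in WT and 9 in the mutants. Shared calls ran in neighbouring genes: the next tested gene was a shared call of the same direction for 12.0% of them, against 1.58% by permutation (permutation p = 1e-04, the smallest that 10000 can give), so blocks of differing genome, or reads shared by neighbouring copies, may contribute.

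For the shared count, of 100 splits of the 9 libraries into 3 groups, 1, the real one, gave 484 genes. The split that only swaps the names of the mutants was left out, as it gives the same count. The highest other gave 419, and it was among the 3 that kept the WT libraries together. The others gave at most 2. An arbitrary grouping of the libraries is thus unlikely to give this count. The splits cannot part genotype from anything else that sets the WT libraries apart as a block. For P1MH against WT the real split gave 1416 genes and the highest of the others 0, and for P3MH against WT 766 and 1, with 1 of the 10 splits as large in each, which are too few for a share under 0.05.

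The third pattern is the fall of cell cycle genes with the rise of genes of the embryo and aleurone list. The list's members OSH1 and RAB16D lay below the filter of 1 RPKM and were not tested, and VP1 did not pass. A larger share of storage transcripts is not the whole source of the fall in P1MH. All 6 cell cycle genes lower in P1MH stayed called after median-ratio rescaling, and the list's median was then -0.73. In P3MH the 1 call, that of PCNA, was lost under this rescaling, and the list's median was -0.44. A larger embryo share of the seed stays open. In P1MH the 7 embryo genes moved apart by more than their errors (heterogeneity Q of 21.4, above the 95th percentile of simulations with 1 common shift, and 22.9 against a 95th percentile of 17.2 with a pseudocount of 0.1). This rests on 2 genes, since Q was 7.56 against 14.9 without VP1, and was also below that percentile without RAB16A. A later seed stage within the harvest window is a candidate explanation that cannot be told apart from genotype: the cell cycle list also had a negative median in P3MH (-0.55), and the labels give only a range of days. An effect of the RBP-P changes stays among the open explanations.

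LOC_Os01g16140, higher in P3MH alone of the 2 lines, lies 47.2 kilobases from RBP-P, 5 tested genes away. A difference linked to the RBP-P locus in that line may be the cause, as a hypothesis. The chance that 1 of 5 random tested genes lies as close was 0.00311. That test was made because the position had been seen, so it restates the position and adds no support of its own.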
